A study of Mus musculus with 16 samples.

How the data were processed

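Liver RNA was measured in 16 male C57BL/6J mice kept at 29 degrees C, within the thermoneutral range of the species, on a diet rich in palm oil fat (40 kcal%) and fructose (20 kcal%) with 0.02% cholesterol. The labels call this a model of metabolic dysfunction-associated steatohepatitis (MASH), a fatty liver disease with inflammation and scarring. Per the labels, 8 mice received the vehicle (1.5% carboxymethyl cellulose and 0.2% Tween-20) and 8 received EVT0185 at 100 mg/kg, and each sample is a separate biological replicate. The age of the mice, the length and route of dosing and the feeding state at collection are not given in the sources used here.

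Per the labels' protocols, total RNA was isolated with a column kit and hybridized to the probe pairs of the nCounter Fibrosis Panel. On this platform each RNA molecule is counted through a fluorescent barcode, without amplification. Per the series' design text, the authors normalized the counts in nSolver 4.0 by a global geometric mean over a panel of 760 genes. The deposited values are on a log2 scale and hold the 760 panel genes, with no rows of control probes. In each of the 16 samples, 2 to the power of the deposited value was a whole multiple of 1 step for 100% of the values, within 0.1 of a count. Each deposited value was therefore the log2 of a whole count times 1 factor per sample, with no background subtracted and no pseudocount. The mean log2 value over the 760 genes still differed between samples, so the factor did not equalize their geometric mean, and which genes set it is not given in the sources used here. The factor had a mean of 0.985 in vehicle and 1.01 in EVT0185 animals.

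The recovered total count per sample ranged from 1462994 to 1850800. It was 1724054 ± 127413 (SD, n = 8) in vehicle and 1632335 ± 122814 (SD, n = 8) in EVT0185 animals, a difference within the spread between animals (exact permutation p = 0.162). The 10 most abundant genes took 48.7% to 53.1% of the counts of a sample, and the most abundant were Apoa2 and Scd1. Over the 612 tested genes the median counting SD was 0.095 and the median SD between animals of a group 0.25 on the log2 scale. Counting made up over 50% of the variance for 55.6% of the 153 genes with the lowest mean count and for 7.19% of the other 459. Among the 56 pairs of animals of the same group, the chi-square per degree of freedom of their counts was 11.6 or more, so no sample was a copy of another of its group.

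Gene names were used as the table gives them. Of the 760 names, 758 matched a current symbol and 2 a synonym in the RefSeq gene table of assembly GRCm38.p6, which served for names alone. The table names no genome build, so no coordinates are given. In 4 rows, several near-identical genes share 1 probe and are named together, such as Cyp4a10/31/32.

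The 612 genes with a mean normalized value of at least 20 over all samples were tested, and 148 below this floor were not. The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a variance trend, on the deposited log2 values of the 16 samples with no covariate. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test had been planned on log2 of the value plus a pseudocount and was run on the values as deposited, since these were already log2. SE is the moderated standard error from limma, and fold changes are EVT0185 over vehicle.

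Before the data were examined, 32 gene lists were written: matrix, fibrosis signalling, lipid metabolism, stress, inflammation and markers of the cell types that a piece of liver could hold. The 27 lists with at least 4 tested members were analysed. Some genes belong to more than 1 list, so calls of lists that share members are not independent. For each animal the mean log2 value of the tested members was taken, and group means were compared by a two-sided exact permutation test over all 12870 assignments, with Benjamini-Hochberg adjustment over the 27 lists. The smallest p this test can give is 0.000155. The cholesterol synthesis, Kupffer cell, B and plasma cell, dendritic and mast cell and cholangiocyte lists had 0, 3, 2, 3 and 1 tested members and were not analysed here. Camera, which compares a list with all other genes, was run with a preset correlation of 0.01 and with an estimated correlation. Fry, which tests whether members move on balance one way, was run beside it.

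The genes named were set by a rule fixed before the data were examined. They are the 10 largest increases and the 10 largest decreases past the threshold, 10 genes fixed by name, and for each analysed list the 3 members with the smallest p. This gave 90 genes. Of the 10 fixed by name, 8 are among the genes of the table and Acly and Acss2 were not analysed here. Lox lay under the floor. Further genes are named where they complete a small count, and these were chosen after their values were seen. Not every gene that this rule names is reported here.

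Alternatives were centring each sample on its median, quantile normalization, pseudocounts of 1 and 20, no floor and a floor of 100, the replicate number as a block, no variance trend, sample quality weights, an exact rank-sum test per gene, the first principal component as list score and leaving out each animal in turn. The limma voom method on the recovered counts was run in place of the planned count model, since the deposited values are log2 and not counts. Re-centring on 22 reference genes was not run because 0 of them are among the genes analysed. Replicate numbers are shared by the groups, but nothing in the labels pairs the animals.

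The scripts were tested on simulated data in which 100 of 612 genes changed, in 20 data sets with the means and spreads of this comparison. A log2 change of 0.5 was recovered for 69.5% of genes and a change of 1 for 95.6%, and 2.23% of calls were false on average. In 20 data sets with no change, 0 had any gene or list past the threshold. Of lists shifted by 0.5, 45% were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.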

Results

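Livers of 8 vehicle-treated and 8 EVT0185-treated mice with diet-induced MASH were compared on a panel of 760 genes of fibrosis, inflammation and metabolism. The series describes EVT0185 as an inhibitor of enzymes of acetyl-CoA metabolism, and the comparison asks which liver transcripts differ after dosing at 100 mg/kg. Values are nCounter counts normalized by the authors, on a log2 scale. Total counts recovered from them ranged from 1462994 to 1850800 per sample.

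The fatty acid oxidation list rose in EVT0185 livers, while the complement, collagen, hepatocyte and antigen presentation lists fell, calls of the exact permutation test of which none passed in camera with an estimated correlation. The complement and hepatocyte lists share members, so their falls are not independent. The largest increase was in the probe shared by Cyp4a10, Cyp4a31 and Cyp4a32, fatty acid hydroxylases induced by PPAR-alpha, at 9.01-fold (log2 3.17, SE 0.19, limma adjusted p = 1.01e-09). The largest decrease was in Apoa4, an apolipoprotein secreted by liver and intestine, which was 19.9-fold lower (log2 -4.32, SE 0.45, limma adjusted p = 1.54e-06). Both separated all 8 EVT0185 animals from all 8 vehicle animals. Of 612 genes tested, 200 passed the threshold in limma, 68 higher and 132 lower in EVT0185, and 10 of the higher and 15 of the lower genes changed at least 2-fold. For 42 genes the groups did not overlap, against 0.0155% of genes by chance, and all 42 were past the threshold. The first principal component held 42.1% of the variance and separated the groups (exact permutation p = 0.000155, the smallest possible).

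The balance of directions moved with the scaling. The median gene differed by log2 -0.10, and 34% of the 200 genes were higher, against 53.3% of 180 after centring each sample on its median. Quantile normalization shifted the median gene by 0.12 upward and gave 108 higher and 89 lower genes. Under all 3 scalings 64 genes were higher and 75 lower, and 0 genes were called in opposite directions. Of 27 gene lists, 16 passed the exact permutation test, 2 higher and 14 lower, against 11 after median centring and 8 after quantile normalization, and 6 and 0 in camera with a preset and an estimated correlation.

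**Figure D1:**
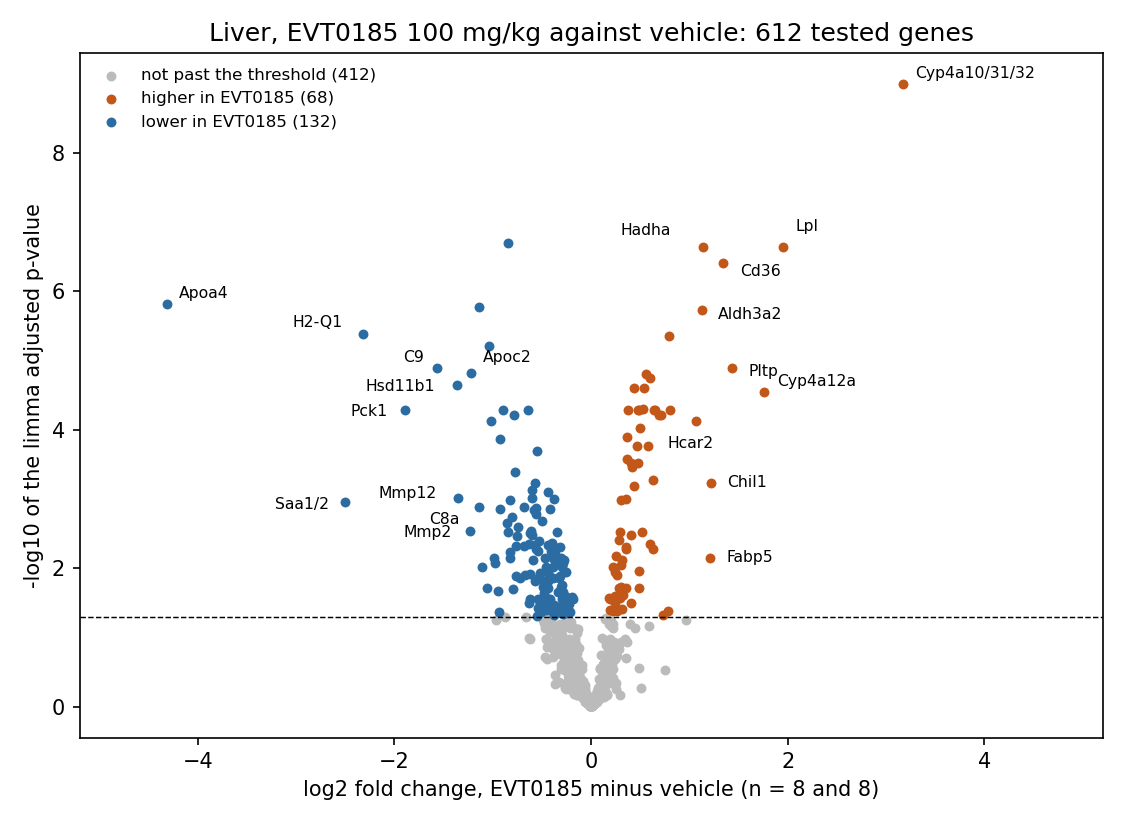
Each point is 1 of 612 tested genes, with its log2 fold change, EVT0185 minus vehicle, on the horizontal axis and -log10 of its limma adjusted p-value on the vertical axis (n = 8 per group, dashed line at 0.05). Orange points are the 68 higher and blue points the 132 lower genes, a split that changed to 96 higher and 84 lower after median centring, and the 10 largest changes each way are named.

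Most tested genes of fatty acid oxidation rose. Of 16 members of the fatty acid oxidation and PPAR-alpha list, 10 rose and 1 fell, also when adjusted over the list alone, and 10 rose and 0 fell under all 3 scalings. Hadha, the alpha subunit of the mitochondrial trifunctional protein, rose 2.21-fold (log2 1.14, SE 0.10, limma adjusted p = 2.32e-07) and Aldh3a2, a fatty aldehyde dehydrogenase, rose by log2 1.12 (SE 0.12). Cyp4a12a, another fatty acid hydroxylase, rose 3.39-fold. The member that fell was Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, at log2 -0.29 (SE 0.10, limma adjusted p = 0.0335), named here after its value was seen, and it was not called under median centring or quantile normalization. The list mean rose by 0.58 (SE 0.064, exact permutation adjusted p = 0.00168), with all 8 EVT0185 animals above every vehicle animal. It was 0.64 after quantile normalization, and in camera it passed with a preset correlation (adjusted p = 1.90e-06) and not with an estimated correlation (adjusted p = 0.337).

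Lpl, Cd36 and Fabp5 rose while 5 apolipoprotein genes of the same list fell and Apoa2 was not called. Of 14 lipid transport and storage genes, 3 rose and 6 fell, against 4 and 6 adjusted over the list alone and 3 and 4 under all 3 scalings. Lpl, the lipase that frees fatty acids from circulating triglyceride, rose 3.87-fold (log2 1.95, SE 0.17, limma adjusted p = 2.32e-07). The fatty acid transporter Cd36 rose 2.54-fold, in all 8 animals above the vehicle range. Fabp5, a fatty acid binding protein, rose by log2 1.21 (SE 0.32). Among secreted apolipoproteins, Apoa1 of high-density lipoprotein fell by 1.04 on the log2 scale (-0.51 after quantile normalization) and Apoc2, the activator of Lpl, was 2.34-fold lower. Pltp, which transfers phospholipid between lipoproteins and was not in the list, rose by log2 1.43 (SE 0.18, limma adjusted p = 1.28e-05). The list mean did not pass (log2 -0.19, SE 0.10, exact permutation adjusted p = 0.105) and was -0.10 after median centring and -0.075 after quantile normalization (adjusted p = 0.436 and 0.521). It passed with the replicate block (adjusted p = 0.0301), with the first principal component as score (adjusted p = 0.000524) and without vehicle 4 (adjusted p = 0.0387).

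Several lipogenic enzymes rose, though their list did not pass. Of 10 members, 4 rose and 1 fell, against 6 and 1 adjusted over the list alone and 2 and 1 under all 3 scalings. Acacb, an acetyl-CoA carboxylase, rose by log2 0.63 (SE 0.16, limma adjusted p = 0.0052). Scd1, which desaturates fatty acids, rose by log2 0.48 (SE 0.14). Elovl6 and Fasn, named after their values were seen, were the other risen members. Srebf1, the transcription factor that drives lipogenesis, fell by 0.60 on the log2 scale (SE 0.14, limma adjusted p = 0.00335). The list mean differed by 0.43 (SE 0.20, exact permutation adjusted p = 0.0727). It passed after median centring (adjusted p = 0.0298), in camera with a preset correlation (adjusted p = 0.0397, and 0.837 with an estimated correlation), with the replicate block (adjusted p = 0.0301), with a floor of 100 (adjusted p = 0.0456), with the first principal component as score (adjusted p = 0.0272) and without vehicle 1 or EVT0185 3 or 8 (adjusted p from 0.0386). Scd1, at 0.14, and Fasn were not called after quantile normalization. Scd1 was, after Apoa2, the most abundant gene on average. Quantile normalization gives each rank the same value in every sample, so it can hardly show a rise of a top-ranked gene. The lost call of Scd1 therefore says little.

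**Figure D2:**
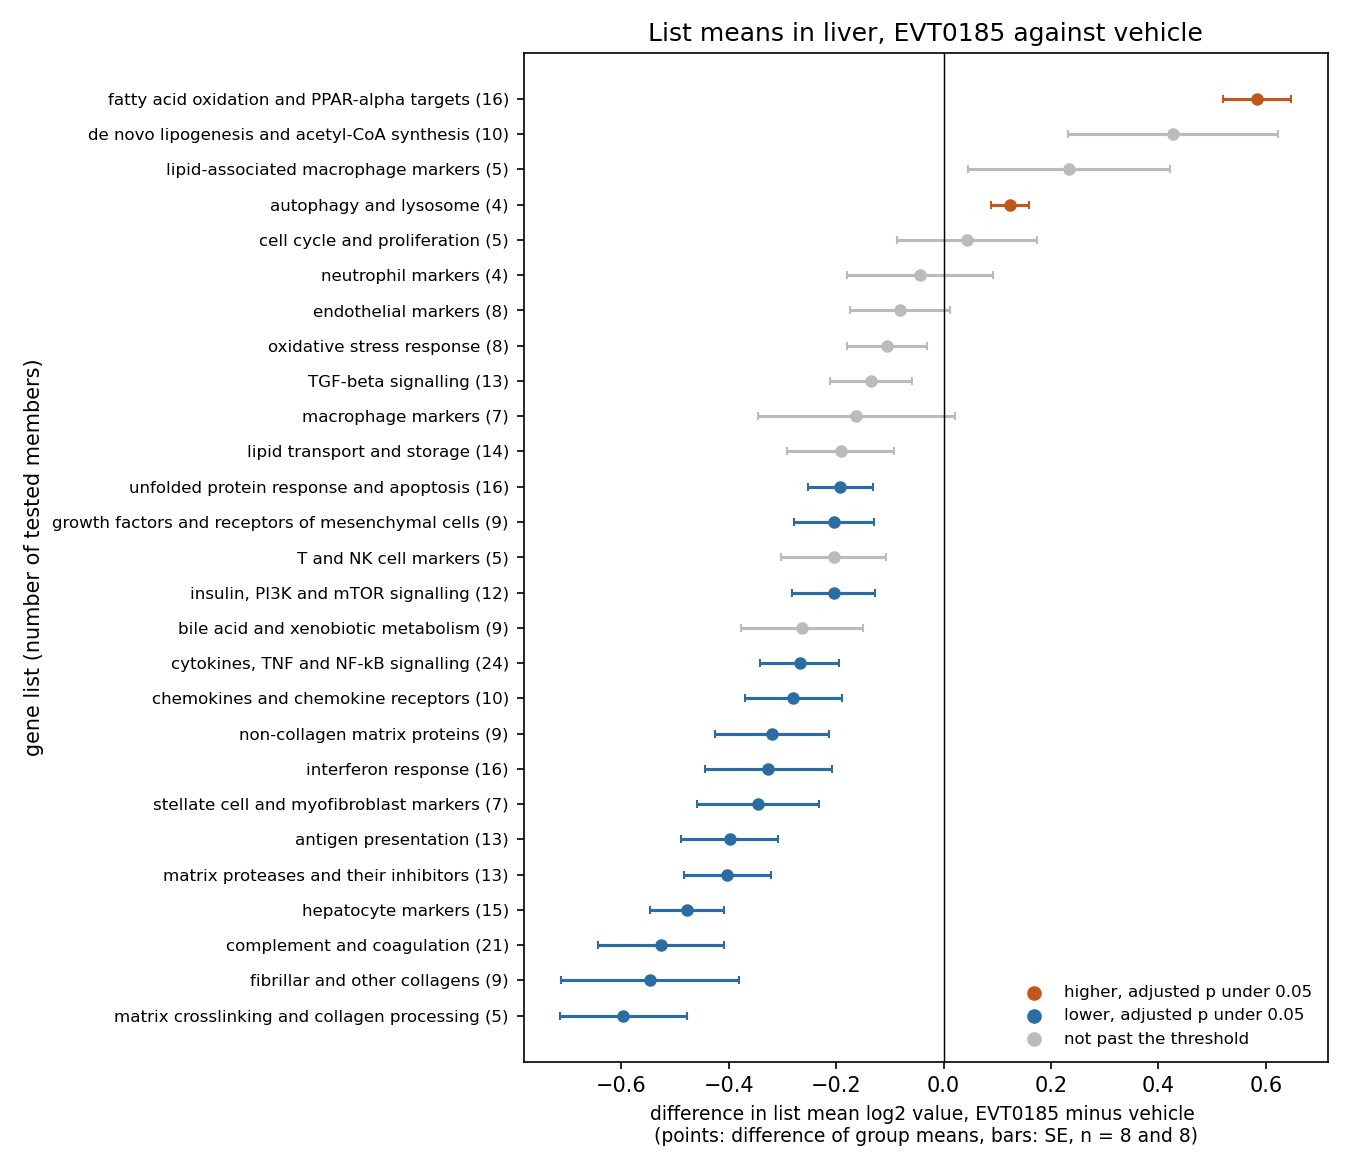
Points are the difference in the mean log2 value of each of 27 gene lists, EVT0185 minus vehicle, and bars are the SE (n = 8 per group, vertical line at 0, tested members in parentheses). Blue lists were lower and orange lists higher by the exact permutation test, grey lists did not pass, and the range runs from -0.60 for matrix crosslinking to 0.58 for fatty acid oxidation, with the neutrophil and endothelial lists changing sign after median centring.

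Collagen genes were lower in EVT0185 livers. Of 9 collagens, 5 fell, also 5 adjusted over the list alone, and 4 under all 3 scalings. Col1a1 and Col1a2, the chains of type I collagen, were 1.93-fold (log2 -0.95, SE 0.30, limma adjusted p = 0.0213) and 1.8-fold lower (log2 -0.85, SE 0.19, limma adjusted p = 0.00295). Col3a1, of type III collagen, was 1.65-fold lower (limma adjusted p = 0.0137), and Col6a3 fell by 0.92 on the log2 scale (SE 0.19). The collagen list mean fell by 0.55 (SE 0.17, exact permutation adjusted p = 0.013), with 6 of 8 EVT0185 animals below every vehicle animal. It was -0.42 after quantile normalization, and the call ended in camera (adjusted p = 0.0704 with a preset and 0.837 with an estimated correlation). The endothelial marker mean differed by -0.081 (exact permutation adjusted p = 0.445; -0.15 without vehicle 4 and -0.036 without EVT0185 3), and the stellate cell and hepatocyte marker means are given below. Col3a1 was not past the threshold in an exact rank-sum test (adjusted p = 0.0768).

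Enzymes and chaperones of collagen processing fell too. Of 5 members of the crosslinking and processing list, 4 fell, against 5 adjusted over the list alone and 3 under all 3 scalings. P4hb, the beta subunit of prolyl 4-hydroxylase and a protein disulfide isomerase, was 1.79-fold lower with no overlap between the groups (log2 -0.84, SE 0.071, limma adjusted p = 2.00e-07). The collagen prolyl hydroxylase P3h3 fell by 0.63 and the collagen chaperone Serpinh1 by 0.46 on the log2 scale. This list mean fell by 0.60 (SE 0.12, exact permutation adjusted p = 0.00168, and adjusted p = 0.0397 with a preset and 0.562 with an estimated correlation in camera).

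Proteases and other matrix proteins also moved. Of 13 proteases and inhibitors, 6 fell and 1 rose, likewise adjusted over the list alone, and 5 and 1 under all 3 scalings. The macrophage elastase Mmp12 was 2.56-fold lower (SE 0.27 on the log2 scale) and the gelatinase Mmp2 was 2.35-fold lower, while the lysosomal protease Ctsd rose by log2 0.30 (SE 0.067). Timp1, an inhibitor of matrix proteases, differed by log2 -0.31 (SE 0.21, limma adjusted p = 0.283), and by -0.19 without vehicle 8 and -0.13 after quantile normalization. The mean normalized value of Timp1, 20.3, lay at the floor, so the missing call says little. The protease list mean fell by 0.40 (SE 0.081, exact permutation adjusted p = 0.00168, and adjusted p = 0.837 with an estimated correlation in camera). Of 9 non-collagen matrix proteins, 5 fell, also 5 adjusted over the list alone and 4 under all 3 scalings, among them fibronectin (Fn1, log2 -0.62, SE 0.14) and thrombospondins Thbs1 (log2 -0.68) and Thbs2 (log2 -0.59). Thbs1 lay near the floor, at a mean normalized value of 23.8. The mean of the 9 matrix proteins fell by 0.32 (SE 0.11, exact permutation adjusted p = 0.0203, and adjusted p = 0.923 with an estimated correlation in camera). That call ended after quantile normalization (log2 -0.23, adjusted p = 0.0721) and after median centring (log2 -0.22, adjusted p = 0.0726).

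The list written for stellate cells and myofibroblasts, the collagen-producing cells of the liver, was partly lower. Its members Acta2, Pdgfrb, Reln, Vim and Ddr2 were not called over all tested genes. Of 7 members, 2 fell, against 4 adjusted over the list alone: S100a4, at log2 -0.77 (SE 0.19, limma adjusted p = 0.0048), and Mylk, a kinase of contractile cells, at -0.42 (limma adjusted p = 0.0405). Acta2, smooth muscle actin, differed by log2 -0.21 (SE 0.25, limma adjusted p = 0.571), from -0.37 without vehicle 4 to -0.062 without EVT0185 3, and Pdgfrb by -0.27 (SE 0.19, limma adjusted p = 0.297), or -0.17 without EVT0185 3 and -0.083 after quantile normalization. The list mean fell by 0.35 (SE 0.11, exact permutation adjusted p = 0.0179, and adjusted p = 0.837 with an estimated correlation in camera). The list call ended after median centring (log2 -0.25, adjusted p = 0.0599) and after quantile normalization (log2 -0.19, adjusted p = 0.157), and the call of Mylk ended with the replicate block (adjusted p = 0.0569) and without vehicle 1, 2, 3, 5, 6 or 8 or EVT0185 1, 2, 3 or 6 (adjusted p up to 0.0831).

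Fibrosis signalling genes changed in few members. Of 13 TGF-beta pathway genes, 2 fell, also 2 adjusted over the list alone: the receptor Tgfbr1 (log2 -0.42, SE 0.087, limma adjusted p = 0.00138) and the ubiquitin ligase Smurf1 (log2 -0.41, SE 0.10). Tgfb1 itself differed by log2 -0.084 (SE 0.091, limma adjusted p = 0.529), and the list mean did not pass (log2 -0.14, exact permutation adjusted p = 0.131), with -0.039 after median centring and -0.0066 after quantile normalization (adjusted p = 0.58 and 0.921). Of 9 mesenchymal growth factors and receptors, Vegfb, a vascular growth factor, rose by log2 0.56 (SE 0.072, limma adjusted p = 1.56e-05) and 0 fell, likewise adjusted over the list alone. Their mean fell by 0.20 (SE 0.074, exact permutation adjusted p = 0.0294, and adjusted p = 0.948 with an estimated correlation in camera), the opposite sign to its called member. That call ended after median centring (-0.11, adjusted p = 0.0599), quantile normalization (-0.069, adjusted p = 0.182), with no floor (adjusted p = 0.098), a floor of 100 (adjusted p = 0.0607) and the replicate block (adjusted p = 0.0777) and without vehicle 3, 6 or 8 or EVT0185 2 or 3 (adjusted p up to 0.0601). Smurf1 was not called after quantile normalization, and Tgfb1 turned sign under both scalings and was -0.14 without vehicle 4, -0.054 without vehicle 6 and -0.049 without EVT0185 2.

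Complement and coagulation genes fell as a list. Of 21 members, 13 fell and 0 rose, against 16 lower adjusted over the list alone and 9 lower under all 3 scalings, and C3 was not called. C9, of the terminal complement pore, was 2.97-fold lower in all 8 animals below the vehicle range (log2 -1.57, SE 0.20, limma adjusted p = 1.28e-05), C8a fell by 1.14 on the log2 scale, the protease C1s1 by 0.93 and the regulator Cfi by 0.55. The list mean fell by 0.53 (SE 0.12, exact permutation adjusted p = 0.00168, and adjusted p = 0.0007 with a preset and 0.837 with an estimated correlation in camera). The shared probe of Saa1 and Saa2, acute-phase apolipoproteins outside the lists, was 5.65-fold lower (log2 -2.50, SE 0.51, limma adjusted p = 0.00112).

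Hepatocyte genes fell as a list, with 8 of 15 members lower and 1 higher, against 10 and 1 adjusted over the list alone and 4 and 1 under all 3 scalings. Pck1, an enzyme of gluconeogenesis, was 3.72-fold lower (log2 -1.90, SE 0.28, limma adjusted p = 5.17e-05), and Fbp1, of the same pathway, fell by 0.85 on the log2 scale (SE 0.19). The list mean fell by 0.48 (SE 0.069, exact permutation adjusted p = 0.00168, and adjusted p = 0.0397 with a preset and 0.783 with an estimated correlation in camera), and 7 of 8 animals lay below every vehicle animal. Its members Fga, Fgb, Fgg, Kng1 and Plg are also in the complement and coagulation list. Plg is in the protease list too, and Pck1 in the insulin list, so the falls of these lists are not independent. Hsd11b1, which regenerates active glucocorticoid and was in no list, was 2.57-fold lower. Of 9 bile acid and xenobiotic genes, 2 fell, also 2 adjusted over the list alone: the bile salt pump Abcb11 (log2 -0.44, SE 0.086) and Cyp27a1, of bile acid synthesis (log2 -0.57, SE 0.14). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.97 (SE 0.38, limma adjusted p = 0.0564), and the list did not pass (log2 -0.26, exact permutation adjusted p = 0.0612), with -0.17 after median centring and -0.15 after quantile normalization (adjusted p = 0.331 and 0.257). Cyp7a1 passed with sample weights (adjusted p = 0.00425), with the replicate block (adjusted p = 0.0397) and without vehicle 1 or 4 or EVT0185 2 (adjusted p from 0.00324), and the list with a pseudocount of 20 (adjusted p = 0.0479), with a floor of 100 (adjusted p = 0.0456) and without vehicle 1 or 4 or EVT0185 4 (adjusted p from 0.0118).

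**Figure D3:**
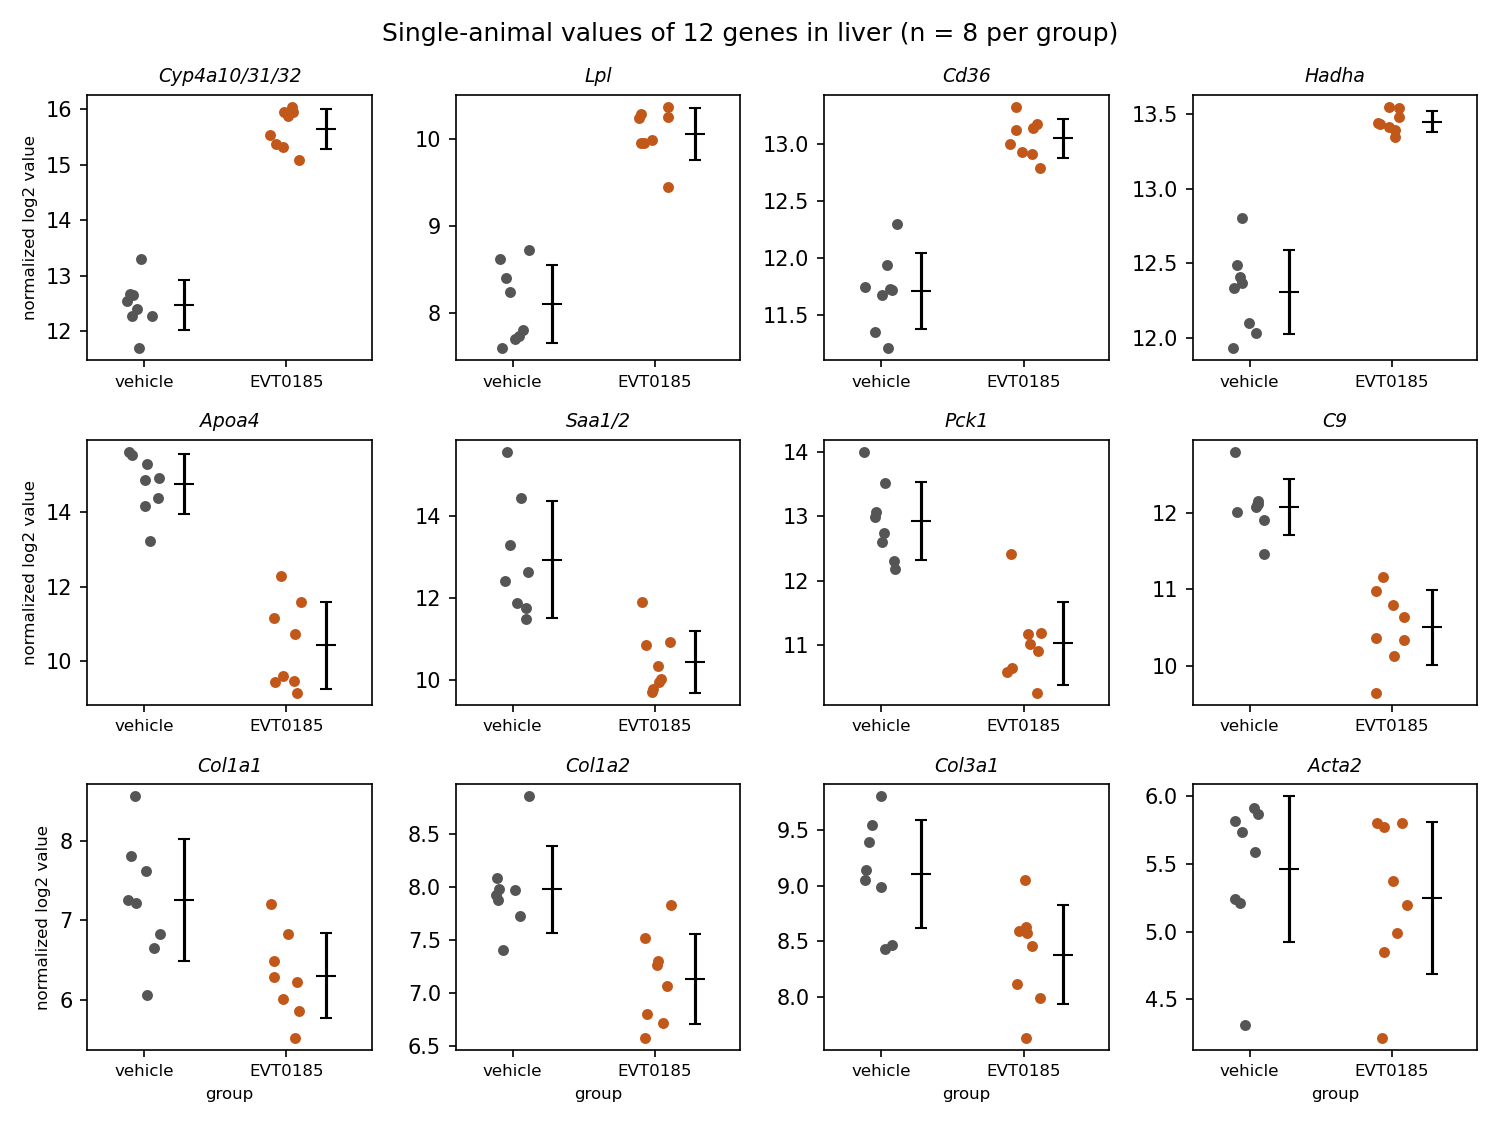
Each panel shows the normalized log2 value of 1 gene in the 8 vehicle (grey) and 8 EVT0185 (orange) animals, with the group mean and SD in black beside the points, and its own vertical axis. The groups did not overlap for Cyp4a10/31/32, Lpl, Cd36, Hadha, Apoa4 and C9, while Acta2 overlapped and its difference of log2 -0.21 changed sign after quantile normalization.

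Antigen presentation genes fell as a list, with 8 of 13 members lower and 0 higher, against 10 lower adjusted over the list alone and 4 lower under all 3 scalings. The class II genes H2-Aa, H2-Ab1 and H2-Eb1, which present peptides to helper T cells, fell by 0.82, 0.75 and 0.80 on the log2 scale (SE 0.16, 0.17 and 0.17). H2-Q1, a class I gene outside the list, was 4.98-fold lower (log2 -2.32, SE 0.26, limma adjusted p = 4.06e-06), a value that is uncertain because class I genes are close in sequence. The list mean fell by 0.40 (SE 0.09, exact permutation adjusted p = 0.00559, and adjusted p = 0.048 with a preset and 0.837 with an estimated correlation in camera), while the macrophage marker mean differed by -0.16 (exact permutation adjusted p = 0.445), and by -0.25 without vehicle 2, -0.033 without vehicle 3 and -0.083 without EVT0185 5. The macrophage mean was -0.066 after median centring and -0.019 after quantile normalization (exact permutation adjusted p = 0.796 and 0.921).

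Several interferon response genes fell, in numbers that depended on the scaling. Of 16 members, 7 fell and 1 rose, against 8 and 1 adjusted over the list alone, 4 and 1 after median centring and 1 and 1 under all 3 scalings. Psmb8, an immunoproteasome subunit, was 2.03-fold lower with no overlap between the groups (log2 -1.02, SE 0.16, limma adjusted p = 7.45e-05), and Bst2, a membrane protein that tethers virions, rose by log2 0.60 (SE 0.14). The list mean fell by 0.33 (SE 0.12, exact permutation adjusted p = 0.0213, and adjusted p = 0.837 with an estimated correlation in camera). That call ended after median centring (log2 -0.23, adjusted p = 0.105) and after quantile normalization (log2 -0.19, adjusted p = 0.157), and with no floor (log2 -0.22, adjusted p = 0.116).

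Chemokines and cytokines changed in a minority of members. Of 10 chemokine genes, 3 fell and 1 rose, likewise adjusted over the list alone, and 2 and 1 under all 3 scalings: Cxcl12 fell by 0.60 on the log2 scale (SE 0.12, limma adjusted p = 0.000728), the monocyte receptor Ccr2 by 0.83 (SE 0.22) and Cxcr4 by 0.52, and Cxcr1 rose by log2 0.49. Of 24 cytokine and NF-kB genes, 5 fell and 1 rose, against 4 and 1 adjusted over the list alone and 3 and 1 under all 3 scalings. The interleukin 1 receptor partner Il1rap fell by 0.79 (SE 0.12, limma adjusted p = 6.19e-05) and the kinase Ikbkb by 0.38 on the log2 scale. List means fell by 0.28 for chemokines (SE 0.09, exact permutation adjusted p = 0.0199, and adjusted p = 0.837 with an estimated correlation in camera) and by 0.27 for cytokines (SE 0.074, exact permutation adjusted p = 0.00719, and adjusted p = 0.837 with an estimated correlation in camera). After quantile normalization neither list passed (-0.10 and -0.12, adjusted p = 0.182 and 0.0536), nor did the chemokine list after median centring (-0.18, adjusted p = 0.0627), where the cytokine list was -0.17 (adjusted p = 0.0382), and Cxcr4 was not called after it or after median centring. The cytokine call also ended with no floor (log2 -0.12, adjusted p = 0.098), and the call of Cxcr1 with the replicate block (adjusted p = 0.0597). Cxcr1 lay near the floor, at a mean normalized value of 26.2.

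Marker lists of immune and endothelial cells did not pass the test. Of 7 macrophage markers, Ccr2 and Cd68 fell, also 2 adjusted over the list alone, and the mean differed by -0.16 (SE 0.18, exact permutation adjusted p = 0.445). Fcer1g, at log2 -0.32, was not called. Nor were 4 members named after their values were seen: Csf1r and Cd14, each at -0.14, Marco at 0.51 (SE 0.56) and Cd163 at 0.29 (SE 0.45). Marco and Cd163 varied widely and went against the other members, so the mean does not show that macrophage content was unchanged. Of 5 lipid-associated macrophage markers, 3 rose (Lpl, Fabp5 and Ctsd) and 2 fell (Mmp12 and Spp1, the latter named after its value was seen), likewise adjusted over the list alone, with a mean difference of 0.23 (SE 0.19, exact permutation adjusted p = 0.271). Of 4 neutrophil markers, Cxcr1 rose and Csf3r fell, likewise adjusted over the list alone, and the mean differed by -0.043 (SE 0.14, exact permutation adjusted p = 0.761). Cxcr1 and Csf3r lay near the floor, at mean normalized values of 26.2 and 22.1. Among 26 T and NK cell markers measured, only 5 were tested, and Cd3e, Cd4 and Cd8a were among those under the floor. Nkg7, Lag3 and Il2ra lay near the floor, at mean normalized values of 22.4, 25.8 and 28. The list therefore says little about these cells. Of these 5 T and NK cell markers 0 passed, also adjusted over the list alone (mean -0.20, SE 0.10, exact permutation adjusted p = 0.0813, and -0.11 after median centring and -0.027 after quantile normalization, adjusted p = 0.58 and 0.871), and of 8 endothelial markers 0 passed, likewise (mean -0.081, SE 0.093, exact permutation adjusted p = 0.445). The sign of the neutrophil and endothelial means turned after median centring, that of the neutrophil mean also without vehicle 3, and the calls of Cd68, Csf3r and Spp1 ended there, those of Cd68 and Csf3r also by the exact rank-sum test (adjusted p = 0.0967 and 0.0602). Cd68 also ended without vehicle 5 or 6 or EVT0185 1, 2 or 8 (adjusted p up to 0.0614) and Csf3r without vehicle 3, 4, 5 or 6 or EVT0185 2, 4, 5 or 7 (adjusted p up to 0.0764), while the T and NK cell list passed without vehicle 1 or EVT0185 5 (adjusted p from 0.0145).

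Stress response lists held changes in both directions. Of 16 unfolded protein response and apoptosis genes, 7 fell and 3 rose, likewise adjusted over the list alone, and 6 and 3 under all 3 scalings. Fas, the death receptor, rose by log2 0.48 (SE 0.085, limma adjusted p = 0.0003), while Xbp1, a transcription factor of the unfolded protein response, fell by 0.39 on the log2 scale. The list mean fell by 0.19 (SE 0.06, exact permutation adjusted p = 0.0126, and adjusted p = 0.923 with an estimated correlation in camera), and was -0.10 after median centring (adjusted p = 0.0488) and -0.069 after quantile normalization. Of 8 oxidative stress genes, Sod1 (log2 0.35, SE 0.07) and Txn1 (log2 0.28) rose and Cybb and Ncf4 fell, likewise adjusted over the list alone, the mean difference being -0.11 (exact permutation adjusted p = 0.23), -0.049 without vehicle 3 and -0.0096 after median centring and -0.024 after quantile normalization. Of 5 cell cycle genes Cdk4 rose (log2 0.25, SE 0.069), likewise adjusted over the list alone, with a mean difference of 0.043 (exact permutation adjusted p = 0.761) that turned sign without vehicle 4 or EVT0185 6. The cell cycle mean was 0.14 after median centring and 0.22 after quantile normalization (exact permutation adjusted p = 0.406 and 0.151). The stress list no longer passed after quantile normalization (adjusted p = 0.0913) or with a floor of 100 (adjusted p = 0.0682), nor did Txn1 and Ncf4 after quantile normalization. The call of Cybb ended by the exact rank-sum test (adjusted p = 0.0602) and without vehicle 3, 5 or 6 or EVT0185 2, 3 or 8 (adjusted p up to 0.0629).

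The autophagy and insulin signalling lists had 1 and 2 members past the threshold. Of 4 autophagy and lysosome genes, Map1lc3a, which coats autophagosomes, rose by log2 0.80 (SE 0.12, limma adjusted p = 5.14e-05), likewise adjusted over the list alone. That list mean rose by 0.12 (SE 0.035, exact permutation adjusted p = 0.00944, and adjusted p = 0.612 with a preset and 0.837 with an estimated correlation in camera), with a median member at -0.066, of the opposite sign, and was 0.22 after median centring and 0.26 after quantile normalization. Of 12 insulin, PI3K and mTOR genes, Pck1 and Pik3cb, a PI3K catalytic subunit (log2 -0.39, SE 0.095), fell, also 2 adjusted over the list alone. The mean fell by 0.20 (SE 0.077, exact permutation adjusted p = 0.0359, and adjusted p = 0.948 with an estimated correlation in camera), with Pck1 at -1.90 and the median member at -0.067. The insulin call ended after median centring (-0.11, adjusted p = 0.0599), quantile normalization (-0.092, adjusted p = 0.157), with the replicate block (adjusted p = 0.0777), with the first principal component as score (adjusted p = 0.933) and without vehicle 2, 3, 4, 5, 6 or 8 or EVT0185 1, 2, 3 or 7 (adjusted p up to 0.07).

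Among genes outside the lists, Chil1, a chitinase-like protein, rose by log2 1.21 (SE 0.23, limma adjusted p = 0.000588) and Hcar2, a receptor for hydroxybutyrate, rose by log2 1.07 (SE 0.16, limma adjusted p = 7.45e-05). Both lay near the floor in vehicle livers, at mean log2 values of 4.76 and 4.79.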

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

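Single animals stood apart from the other 7 of their group in 18 of 234 groups of values tested with Dixon's gap ratio, where about 1 in 20, or 11.7, come by chance. The gap ratio was set before the values were seen, and no explanation, technical or biological, was tested for single animals.

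Vehicle 3 held 5 of the 18 values. Its interferon list mean of 8.53 lay above the other vehicle animals, at 7.74 to 8.02, as did its values of Bst2 (12.1, against 11.1 to 11.4), Psmb8 (10.3, against 8.96 to 9.57) and the growth factor receptor Egfr (11.7, against 8.68 to 9.93). Its H2-Q1 value of 5.48 lay below the others, at 6.78 to 7.90. All values here are normalized log2 values or list means of them. Without vehicle 3, 174 genes passed the threshold in limma against 200 with it, and 14 lists against 16.

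Among matrix genes, vehicle 8 had the highest Col1a2 (8.85, against 7.40 to 8.09) and Ccn2 (8.28, against 7.35 to 7.74), a matricellular protein downstream of TGF-beta. Vehicle 4 had the lowest Acta2 (4.31, against 5.21 to 5.91) and the lowest endothelial list mean (6.65, against 7.02 to 7.33). EVT0185 3 had the lowest Mmp2 of its group (3.05, against 4.38 to 5.23). Vehicle 7 had the lowest Mylk (8.28, against 9.09 to 9.47) and the lowest insulin, PI3K and mTOR list mean (7.62, against 8.07 to 8.23). Vehicle 7 also had a low median over the tested genes, 7.63 against a vehicle mean of 7.96, and stood apart on the third principal component, at -9.80.

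Among metabolic and immune genes, Pck1 was 12.4 in EVT0185 8 against 10.3 to 11.2 in the other EVT0185 animals, and Lpl was 9.45 in EVT0185 6 against 9.95 to 10.4. Il1rap was 9.61 in vehicle 1 against 10.2 to 10.6, and Map1lc3a was 8.68 in vehicle 6 against 9.16 to 9.58. EVT0185 5 had the lowest macrophage list mean of its group (6.46, against 7.00 to 7.26) and the highest T and NK cell list mean (4.95, against 4.39 to 4.63).

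Below the floor of 20, where no gene was tested in the main comparison, Ifng, the interferon of T and NK cells, was higher in EVT0185 by log2 0.97 when all 760 genes were tested in limma. Its mean normalized value was 5.98 in vehicle and 10.9 in EVT0185 livers, so the difference rests on few counts. In that test 5 other genes below the floor were lower, all named after their values were seen: the fibroblast protease Fap at log2 -2.13, elastin (Eln) at -0.55, and Il27, Ms4a4a and Ncam1. Mean normalized values in vehicle and EVT0185 livers were 7.65 and 2.02 for Fap, and 5.73 and 3.60 for Il27. Their differences therefore also rest on few counts.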

How the results depend on the processing

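Pseudocount 1, voom and leaving out vehicle 7 with EVT0185 2, the animals of lowest median, were chosen after seeing the data. Of 90 named genes, all kept direction and side of the threshold with pseudocounts of 1 and 20, with no floor and in voom, which called 202 genes including all 200 of the main test. Other settings gave 194 genes with no floor, 170 with a floor of 100 (of 436), 201 without the variance trend, 251 with sample weights, 193 by the exact rank-sum test and 213 without the 2 animals. Leaving out each animal in turn gave 170 to 236 genes, 60 to 71 higher and 103 to 165 lower, and 14 to 19 lists. Counts moved by more than 1.5 times for genes lower after median centring (84 against 132), for genes higher after quantile normalization (108 against 68) and for lists after quantile normalization (8 against 16), with camera at a preset correlation (6) and with camera at an estimated correlation (0). Lower lists went from 14 to 8 after centring, 6 after quantile normalization and 4 and 0 in camera, and higher lists from 2 to 4 as first principal components and 0 in camera at an estimated correlation. With the estimated correlation 2 lists were under 0.05 unadjusted, and fry called 13 lists moving one way and 20 with members in either direction. Camera compares a list with all other genes and the exact permutation test does not. For the scalings and for each sign below the cause was not tested. Signs turned for 6 named genes that were not called and for 5 lists, of which the insulin list had been called. After median centring, Flt4 was at 0.017, Nkg7 at 0.043, Tgfb1 at 0.012, the neutrophil list at 0.053 and the endothelial list at 0.015. After quantile normalization, Acta2 was at 0.018, Flt1 at 0.040, Flt4 at 0.048, Lipa at 0.0066, Nkg7 at 0.13, Tgfb1 at 0.017, the neutrophil list at 0.16 and the endothelial list at 0.054. The neutrophil list was at 0.038 with no floor and at 0.021 without the 2 animals. The insulin list was at 0.11 as a first principal component, where the lipogenesis, lipid transport, oxidative stress, lipid-associated macrophage and neutrophil lists were gained. Against all other genes, as camera compares them with either correlation, the oxidative stress list was at 0.015, the neutrophil list at 0.078 and the endothelial list at 0.040. Leaving out each animal in turn, Flt4 ran from -0.14 to 0.00092, Nkg7 from -0.17 to 0.015, the neutrophil list from -0.10 to 0.040 and the cell cycle list from -0.024 to 0.11; Flt4 turned without vehicle 1, Nkg7 without vehicle 1, EVT0185 1 or EVT0185 4, the neutrophil list without vehicle 3, and the cell cycle list without vehicle 4 or EVT0185 6. With the replicate block, 190 genes passed, 174 of them among the 200, and 16 lists passed, 14 of them among the 16 and the lipogenesis and lipid transport lists gained. Animals of the same number had correlations of their deviations from -0.14 to 0.46, over 0.1 in 5 of 8 pairs. The mean was 0.14, against -0.019 for animals of different numbers, and 2 of 8 vehicle animals correlated best with their own number. The labels pair no animals, so the numbers were not read as pairs, but some structure shared by number stays open. Not run were re-centring on reference genes, 0 of which are among the genes analysed, the planned count model, replaced by voom on the recovered counts, and a pseudocount under 1. The values hold no pseudocount, so the main test was itself run with none. Depth limits the 148 genes under the floor.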

Other observations

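The tests of the scaling and of a longer fast, leaving out animals from the differences between list means and the 9 further gene lists in this part were chosen after the result was seen. The further lists were written from the gene names once the comparison was known, so their calls are not independent of it. Their p-values were adjusted over these 9 lists alone. Camera and fry were not run on them, so their calls lack the check given for the lists written before.

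Genes of the mitochondrial respiratory chain, which passes electrons from nutrients to oxygen, were higher in EVT0185 livers. All 14 tested members rose in limma, and the list mean rose by 0.37 (exact permutation adjusted p = 0.000699), with 7 of 8 EVT0185 animals above every vehicle animal, and by 0.46 after median centring. Genes of gluconeogenesis and glucose handling fell, with 6 of 8 lower and 1 higher and a list mean of -0.67 (exact permutation adjusted p = 0.000466). Apolipoproteins and lipoprotein remodelling genes had 6 of 13 lower and 1 higher (mean -0.50, exact permutation adjusted p = 0.000466), and acute-phase proteins 6 of 11 lower and 1 higher (mean -0.64, exact permutation adjusted p = 0.00112). In endoplasmic reticulum folding and export, through which secreted proteins pass, 9 of 17 genes fell and 0 rose (mean -0.27, exact permutation adjusted p = 0.000466). After median centring and quantile normalization this mean was -0.17 and -0.17, that of gluconeogenesis -0.58 and -0.56, of apolipoproteins -0.40 and -0.39, and of acute-phase proteins -0.54 and -0.55.

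Proteasome and ubiquitin, Notch and Hedgehog, Hippo and chromatin lists did not pass, with means of -0.019, -0.085, 0.039 and -0.024 (exact permutation adjusted p = 0.796, 0.454, 0.821 and 0.860). The Hippo list passed at 0.13 after median centring and at 0.15 after quantile normalization (exact permutation adjusted p = 0.0014 and 0.00035), and the proteasome list at 0.074 after quantile normalization alone (exact permutation adjusted p = 0.0048).

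Chance is argued against, though not excluded, for the number of changed genes and lists. Of 100 splits of the 16 animals into 8 and 8, 1 gave as many genes, the real one, with 200 genes against at most 3 in any other split. For lists, also 1 of 100 splits gave as many, the real one, with 16 lists against at most 5. The 100 splits were drawn from 6435 possible ones. Every other split mixed treated with vehicle animals, which widens the spread within its groups and lowers its counts. Splits also cannot separate the treatment from a batch that the labels do not give.

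More genes were lower than higher, 132 against 68. After centring each sample on its median, 53.3% of the called genes were higher, a share that centring itself draws toward balance. The scaling factor differed by 0.0232 between the groups (exact permutation p = 0.522), while the mean log2 value over the 760 genes, which a global geometric mean over all of them would equalize, differed by -0.10 (exact permutation p = 0.0101). With 0 of the 22 reference genes looked for among the deposited values, a general fall of transcripts and a scaling effect cannot be told apart, and the direction of genes near 0 stays open.

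The fatty acid oxidation list rose by exact permutation, though it did not pass in camera with an estimated correlation (adjusted p = 0.337). The high abundance of its genes is argued against by its median of 0.38, at percentile 99.98 among 10000 random lists matched on mean level, whose median was -0.12. These random lists do not keep the correlation between genes of a list. A single animal is argued against since all 8 EVT0185 list means lay above every vehicle list mean. That separation holds without any 1 animal. The highest adjusted p when each of the 16 animals was left out, 0.0042 by exact permutation, therefore adds nothing to it. A longer fast in EVT0185 animals would raise Pck1, which instead was at log2 -1.90 (limma adjusted p = 5.17e-05), and would lower lipogenesis genes, of which 4 rose and Srebf1 fell, with no call for the list and 2 risen under all 3 scalings. Among these scalings, quantile normalization can hardly show a rise of the abundant Scd1. An effect of EVT0185 on Pck1 itself may mask a fast, and the lipogenesis genes moved both ways, so these values cannot decide on a fast. Activation of PPAR-alpha by EVT0185 or by lipid flux stays a hypothesis not tested here.

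The collagen and antigen presentation lists both fell by exact permutation, though neither passed in camera with an estimated correlation (adjusted p = 0.837 for both). A lower share of all non-hepatocyte cells would lower endothelial markers alike, and the collagen minus the endothelial mean was -0.46 (exact permutation p = 0.00233), and from -0.53 without EVT0185 7 to -0.38 without vehicle 8 when each animal was left out, with p at most 0.00497. A lower share of macrophages behind the antigen presentation genes cannot be told apart from a change in those genes, since the difference between the 2 means, at -0.24, did not pass (exact permutation p = 0.257), though it was -0.37 without EVT0185 5 (exact permutation p = 0.0451) and -0.17 without vehicle 2. Hepatocyte markers fell too, so a shift toward hepatocytes is not seen in the lists. Lower activation of collagen-producing cells may be a candidate explanation, but a lower share of these cells alone was not tested and cannot be told apart from it. Acta2, at log2 -0.21 (limma adjusted p = 0.571), ran from -0.37 without vehicle 4 to -0.062 without EVT0185 3 and decides nothing, and cell counts were not analysed here.

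A pair of hypotheses on animals within a group, 4 relations in all, gave no clear result. If stronger fatty acid oxidation went with lower collagens, the list means would correlate below 0 within the 8 EVT0185 animals. Pearson r was -0.28 (permutation p = 0.499, exact over all orders) and Spearman rho -0.048 (permutation p = 0.935), and r was 0.22 without the 2 animals farthest from the median. Within vehicle animals r was 0.46 (permutation p = 0.254), rho 0.60 (permutation p = 0.132) and r 0.64 without 2. If feeding state set lipogenesis, its list mean would fall with Pck1 in both groups. In vehicle r was -0.52 (permutation p = 0.190), rho -0.45 (permutation p = 0.267) and r -0.062 without 2, and in EVT0185 r was -0.33 (permutation p = 0.468), rho -0.19 (permutation p = 0.665) and r -0.72 without 2. Adjusted over the 4 relations, each p was 0.499.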
